A study of Rattus norvegicus with 8 samples.

How the data were processed

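The series measured messenger RNA in neonatal rat ventricular myocytes, which are heart muscle cells isolated from newborn rats (Rattus norvegicus) and kept in primary culture. Per the labels' protocols, the cells were grown in medium with 5% fetal bovine serum and were either infected with adenoviruses encoding ADGRF5, an adhesion G protein-coupled receptor, or left uninfected. The titles call the uninfected cells a vehicle control, and they are called controls here. No sample received a virus without ADGRF5, so infection and overexpression varied together in every comparison. The design text gives 4 biological replicates in each of 2 conditions, which makes 8 libraries. Messenger RNA was enriched, fragmented and reverse transcribed with random primers, per the labels' protocols. Whether the libraries kept the strand, and from which species the ADGRF5 sequence was taken, was not given in the sources used here.

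The authors deposited one table of read counts per library, as whole numbers per gene that were not normalised. Per the submitters' processing notes, the tools used were Trimmomatic 0.36, STAR 2.5.2b, featureCounts from Subread 1.5.2, and DESeq2. The genome build and the annotation release were not given in the sources used here, and coordinates are those of the count files. The authors also deposited a table of their own comparison, with DESeq2's column names per the file headers. In it the authors gave for each gene a mean signal over libraries (counts divided by size factors), a log2 fold change with its standard error, a test score and a p-value with its adjusted p-value. From its values, that table holds only genes with an adjusted p-value under 0.05 and an absolute log2 fold change above 1. The deposited score column was not used here except to order genes of equal p-value.

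The count files list 32552 genes by Ensembl identifier, and 20443 of them had a count in at least 1 library. The files do not pair these identifiers with gene symbols. The reference table used for names (assembly GRCr8, 47357 rows) held no Ensembl identifiers, so 0 of the 32552 identifiers matched. The 20 pathway lists and 8 cell type marker lists fixed by symbol before the data were examined, and the look-up of Adgrf5 by name, were therefore not analysed here. In their place genes were grouped by chromosome, average abundance, exon length and neighbourhood, as the count files give them. These groups were chosen after the data were examined.

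Total counts ranged from 20320311 to 35446083 per library, so that 3 counts corresponded to between 0.0846 and 0.148 CPM (counts scaled to the total of the library). For shares of counts in a single library, 95% Wilson confidence intervals were computed. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries in a group agreed within sampling noise, and all 8 libraries were kept as separate replicates, as the design text gives them. They were not equally distant, however: the chi-square statistic divided by its degrees of freedom was 5.56 for ADGRF5 1 and 2, 3.75 for ADGRF5 3 and 4 and 3.16 for controls 2 and 3, and between 26.3 and 111 for the 9 other pairs within groups. Exceeding sampling noise does not show that the close pairs are independent cultures.

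Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with group as the only term, TMM scaling and the filterByExpr filter, which kept 13542 genes. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F, and are approximate. CPM per library were scaled with the TMM factors unless the text gives them as shares of all counts. Chromosome groups of at least 10 tested genes were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. These group tests ran on scaled log2 CPM, so the choice of DESeq2 or limma-voom for the genes does not enter them. Values per library were compared by exact two-sided permutation tests, for which the smallest p with 4 against 4 libraries is 0.0286. The 4 such comparisons were adjusted together. All 4 gave the smallest p, which the adjustment leaves unchanged.

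Neighbouring genes were counted along each chromosome over the tested genes in order of start. The calls were permuted 10000 times within deciles of average abundance to give the number of neighbouring pairs expected by chance, and 1000 times for runs of at least 4 genes. Simulated counts, drawn from the libraries' means and sizes with 200 changed genes, tested the procedure for the comparison of ADGRF5 with control. Over 13435 genes tested, 84.7% of the 2-fold and 98.0% of the 4-fold changes were recovered, and 6 of 186 calls were unchanged genes. The simulated libraries were independent, no change exceeded 4-fold, and far fewer genes changed than the 7743 called in the data. The simulation therefore does not give the error rate under close pairs of libraries or so many changes.

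Genes were singled out by a rule fixed before the data were examined: an adjusted p under 0.05, an average log2 CPM of at least 1, all 4 libraries of one group above all 4 of the other, and then the 12 largest rises and the 12 largest falls. The rule's condition on symbols could not be applied. From these, 2 identifiers in each direction are printed, and others are given by position. The rule also took the 3 genes of lowest adjusted p in each direction in the authors' table.

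Alternatives were DESeq2 1.42.0, limma-voom, 3 other scalings, 2 other filters, an adjusted p threshold of 0.01, the replicate number as a block, and leaving out each library in turn. After the data were examined, fits without ADGRF5 libraries 1 and 2, without ADGRF5 libraries 3 and 4, without mitochondrial genes, without mitochondrial genes and the most abundant gene, and with each close pair of libraries summed into 1 replicate were added.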

Results

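Messenger RNA was counted in 8 libraries of neonatal rat ventricular myocytes, 4 from cells infected with an adenovirus encoding ADGRF5 and 4 from uninfected controls. The 4 ADGRF5 libraries held 25151934, 23876135, 20320311 and 24491777 counts in replicates 1 to 4. The 4 control libraries held 21410822, 35446083, 22455439 and 23061933 counts. The comparison asked which genes differ in expression when ADGRF5 is overexpressed, as the title of the series states it. Because the controls were uninfected, each difference below is one between infected, overexpressing cells and uninfected cells.

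One gene on chromosome 9 dominated the ADGRF5 libraries. This gene, ENSRNOG00000011154, lies on the minus strand from 20091099 to 20195566 and has 23 exons and 8569 nt of exon sequence after overlapping exons are merged. It took 4.13%, 4.42%, 9.01% and 9.63% of all counts in ADGRF5 replicates 1 to 4, with 95% Wilson intervals of at most 0.0124 percentage points to either side. In the controls it had 429, 545, 377 and 1477 counts, or 20.04, 15.4, 16.8 and 64.0 CPM (counts scaled to the total of the library). Its mean was 67972 ± 29229 CPM in the ADGRF5 libraries (SD, n = 4) against 29.1 ± 23.4 CPM in the controls (SD, n = 4; exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0286 over 4 comparisons). The gene was picked for the highest mean CPM over all libraries, a rank that its ADGRF5 counts gave it, so this permutation test adds no support of its own. The fitted log2 fold change was 11.28 (SE 0.74, edgeR adjusted p = 8.2e-06), the largest rise among the genes that met the naming rule. It was 12.03 without control replicate 4 and 10.64 without ADGRF5 replicates 3 and 4. The files do not pair identifiers with symbols, so the overexpressed gene was not analysed here by name.

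**Figure D1:**
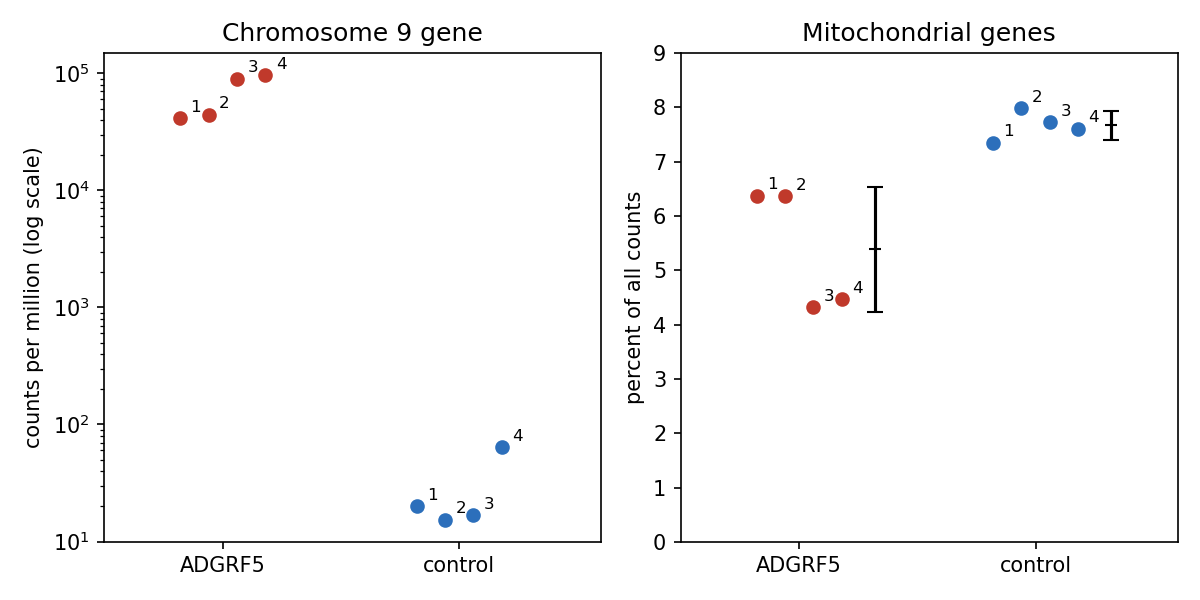
Each point is 1 library, numbered by replicate. The left panel gives CPM of the chromosome 9 gene on a log axis, between 41303 and 96280 in the ADGRF5 libraries and between 15.4 and 64.0 in the controls, and the right panel gives the percent of counts in mitochondrial genes with the mean and SD of each group (n = 4), where each ADGRF5 library lies below each control.

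The ADGRF5 and control libraries differed in the expression of 7743 of the 13542 genes tested, or 57.2%. Of these, 3802 rose and 3941 fell in the ADGRF5 libraries (edgeR, adjusted p under 0.05). Scaling by library totals alone gave 2990 rises and 4737 falls, and upper-quartile scaling gave 3371 and 4443. The balance of rises and falls thus depended on the scaling. Most changes were small, with a median absolute log2 fold change of 0.65 among the called genes. At least a 2-fold change was reached by 1971 genes, of which 775 rose and 1196 fell, and at least an 8-fold change by 46 that rose and 18 that fell. All 4 libraries of one group lay above all 4 of the other in 1831 of the 1971 genes, or 92.9%, and in 53.02% of all tested genes, where chance gives 2.86%. The number of genes that fell at least 2-fold was 1821 without ADGRF5 replicates 1 and 2, and 837 without ADGRF5 replicates 3 and 4. The libraries were not evenly spread within groups: ADGRF5 1 and 2, ADGRF5 3 and 4, and controls 2 and 3 formed close pairs, and with each close pair summed into 1 replicate 4819 genes changed, 2548 higher and 2271 lower, of which 1715 changed at least 2-fold. If the close pairs are not independent cultures, the p-values here are too small, and an exact test of the remaining 2 against 3 replicates cannot go below 0.1.

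**Figure D2:**
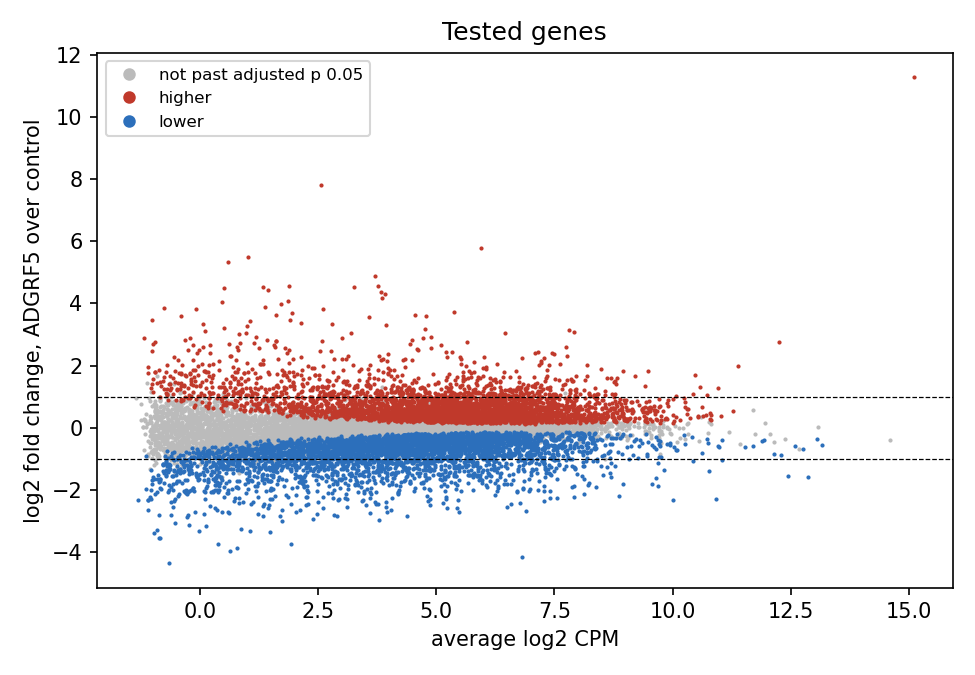
Each point is a tested gene, placed by its average log2 CPM and its log2 fold change (ADGRF5 over control), and coloured by the edgeR call at an adjusted p of 0.05; dashed lines mark 2-fold changes. The chromosome 9 gene stands at the upper right with a log2 fold change of 11.28.

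The libraries separated by group on the first principal component of log2 CPM, which held 72.4% of the variance. On it ADGRF5 replicates 1 to 4 lay at -23.7, -30.6, -61.7 and -60.8, and control replicates 1 to 4 at 44.1, 48.4, 49.4 and 34.9. The second component held 10.2% of the variance and divided both groups. On the second component ADGRF5 replicates 1 to 4 lay at -21.9, -23.2, 10.7 and 16.7, and control replicates 1 to 4 at 8.02, -8.78, -9.08 and 27.6.

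**Figure D3:**
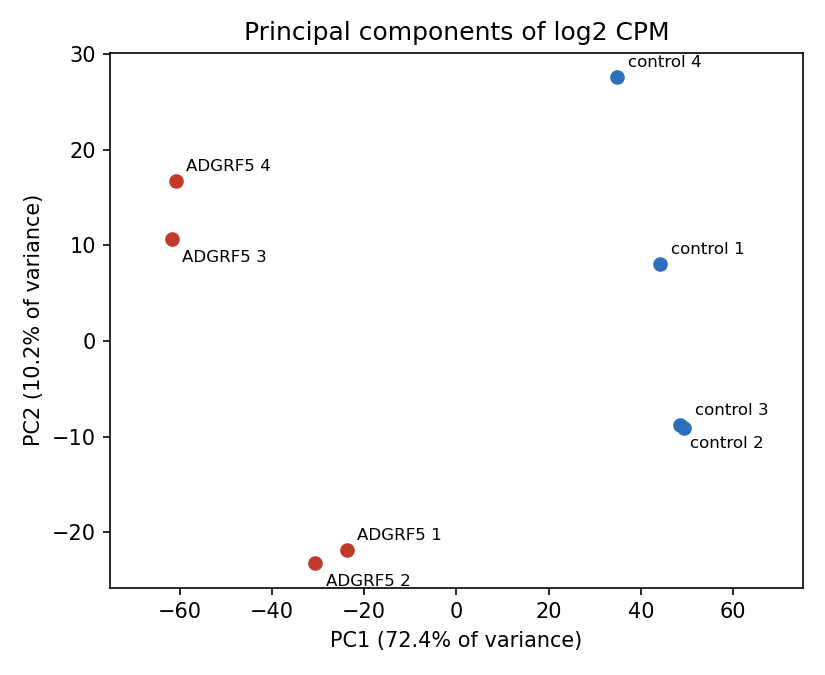
Principal components of log2 CPM over the tested genes, with 1 point per library and the percent of variance on each axis. The first component (72.4%) parts the groups, the ADGRF5 libraries lie between -61.7 and -23.7 on it, and control 4 (34.9) is the control nearest to them.

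The 12 largest rises under the naming rule lay on 10 chromosomes and had log2 fold changes from 4.32 to 11.28. After the chromosome 9 gene came ENSRNOG00000025164, on chromosome 12 from 12403385 to 12407561. It had 201, 220, 297 and 334 counts in ADGRF5 replicates 1 to 4 and 0, 3, 1 and 1 in the controls. Its summed CPM ratio was 230, with an exact 95% counting interval from 98.0 to 708 (log2 fold change 7.81, SE 0.40, edgeR adjusted p = 3.4e-06). Control replicate 2 held 3 of the 5 control counts, and without it the log2 fold change was 8.42. The 12 largest falls lay on 8 chromosomes, with log2 fold changes from -4.18 to -2.82. ENSRNOG00000011754, on chromosome 16 from 79587640 to 79671719, fell from 214 ± 102 CPM to 11.7 ± 9.25 CPM (SD, n = 4 each), which was 18.1-fold (log2 fold change -4.18, SE 0.62, edgeR adjusted p = 0.00047; -5.70 without ADGRF5 replicates 1 and 2, and -3.47 without ADGRF5 replicates 3 and 4). ENSRNOG00000001912, on chromosome 14 from 26662965 to 26737657, fell from 6.74 ± 3.65 CPM to 0.496 ± 0.260 CPM (SD, n = 4 each; log2 fold change -3.75, SE 0.53, edgeR adjusted p = 0.00035). Its log2 fold change was -4.48 without ADGRF5 replicates 1 and 2, and -3.30 without ADGRF5 replicates 3 and 4.

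Abundant genes rose more often than they fell, and scarce genes fell more often than they rose. In the highest decile of tested genes by average CPM, 618 genes rose and 334 fell, with a median log2 fold change of 0.14. In the lowest decile, 142 rose and 270 fell, with a median of -0.19, and in the next lowest 194 rose and 428 fell, with a median of -0.31. The median of the highest decile stayed above 0 with library totals (0.04) and upper-quartile scaling (0.09), while those of deciles 7 and 8 (0.05 and 0.07) fell below 0 with library totals (-0.05 and -0.02), and that of decile 7 also with upper-quartile scaling (-0.0042). Within each library, the median log2 CPM of the highest 2 deciles exceeded that of the lowest 2 by 6.88 ± 0.055 in the ADGRF5 libraries and by 6.58 ± 0.072 in the controls (SD, n = 4 each), a contrast that no scaling factor alters (exact permutation p = 0.0286, adjusted p = 0.0286, higher in 4 of 4 ADGRF5 libraries than in any control). Among the 50 most abundant genes, by contrast, 14 rose, 21 fell and 15 did not pass the test.

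**Figure D4:**
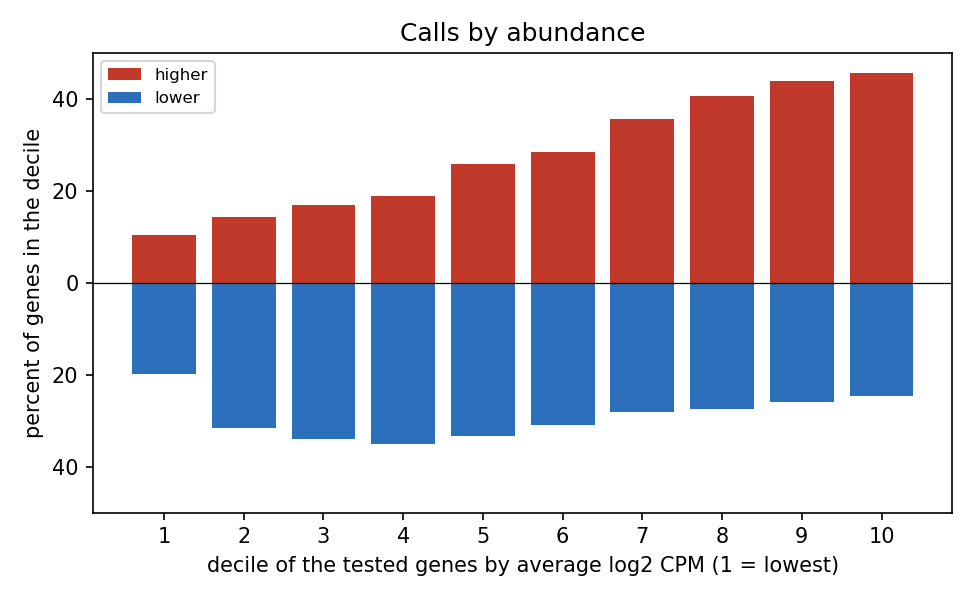
Percent of genes called higher (upward bars) and lower (downward bars) in the ADGRF5 libraries, in each decile of the tested genes by average log2 CPM. Rises grew from 10.5% in the lowest decile to 45.6% in the highest.

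Genes with long exon sequence were called lower more often than short ones. Of 936 tested genes over 6000 nt, 220 rose and 354 fell (median log2 fold change -0.11), and of 1539 genes of up to 1000 nt, 343 rose and 331 fell (median 0.02). The long genes were also more abundant (median log2 CPM 5.57 against 2.63). Genes were not matched for abundance, so the shares called may partly reflect it. For falls, however, the trend with abundance ran the other way at these medians. Of all tested genes, 28.1% fell in abundance decile 7, which holds the long genes' median. In decile 3, which holds the short genes' median, 34.0% fell. Over all tested genes the Spearman rank correlation of log2 fold change with exon length was -0.066. Within libraries, the median log2 CPM of the long genes exceeded that of the short genes by 2.88 ± 0.045 in the ADGRF5 libraries and by 3.04 ± 0.079 in the controls (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0286). The groups did not overlap but came close, with 2.92 in the highest ADGRF5 library and 2.93 in the lowest control.

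The mitochondrially encoded genes counted here, which code for parts of the respiratory chain and for the organelle's own transfer RNAs, took a smaller share of counts in the ADGRF5 libraries. Their share was 6.38%, 6.37%, 4.32% and 4.47% in ADGRF5 replicates 1 to 4 and 7.35%, 7.99%, 7.73% and 7.61% in the controls. The means were 5.38 ± 1.14% and 7.67 ± 0.265% (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0286). With the chromosome 9 gene left out of the totals, they were 5.75 ± 1.05% and 7.67 ± 0.265% (SD, n = 4 each). Of the 24 mitochondrial genes tested, 10 fell and 0 rose, with a median log2 fold change of -0.41. This count depended on single libraries: 2 fell without ADGRF5 replicate 3, 3 without ADGRF5 replicate 4, 2 without control replicate 2, 6 without control replicate 3 and 6 without control replicate 4. It was 1 with the close pairs of libraries summed, 3 without ADGRF5 replicates 3 and 4 together, and 16 with library totals. As a set they did not pass camera over 22 chromosome groups (adjusted p = 0.067, and 0.99 with an estimated correlation). They passed camera without ADGRF5 replicate 1 (adjusted p = 0.037), without ADGRF5 replicate 2 (0.013), without control replicate 1 (0.018) and with library totals (0.047). They also passed it without ADGRF5 replicates 1 and 2 together (0.00052), and with the replicate block, which is taken up further below. With an estimated correlation none of these calls held (camera adjusted p between 0.70 and 0.99).

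None of the 21 nuclear chromosome groups differed from the remaining genes in camera, with a lowest adjusted p of 0.99 for the nuclear groups. At an unadjusted p under 0.05, 1 of the 22 groups passed camera with the preset correlation, the mitochondrial genes (p = 0.0031). A different one, chromosome 11, passed with the estimated correlation (p = 0.025). By fry, which asks whether a group's genes move on balance in one direction and does not compare them with other genes, 14 groups passed an adjusted p of 0.05, 12 of them higher and 2 lower. As a set, the 12 higher calls did not hold. With library totals 17 groups passed, all lower, with upper-quartile scaling 1 passed higher and 14 lower, and without ADGRF5 replicates 1 and 2 it was 4 higher and 15 lower. The 2 lower groups, chromosome X and the mitochondrial genes, passed as lower in each of these fits too. Without ADGRF5 replicates 3 and 4, no group passed as lower. With the close pairs of libraries summed 0 groups passed, and with single libraries left out between 4 and 15 did. The 2 lower calls did not both hold in any of these single-library fits. Only 1 group passed as lower without ADGRF5 replicate 1, ADGRF5 replicate 2 or control replicate 1. Without ADGRF5 replicate 3 or 4, or control replicate 2, 3 or 4, 0 groups passed as lower. The share of changed genes ranged from 54.9% to 61.6% over the nuclear groups.

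Genes changed at least 2-fold in one direction lay side by side more often than chance gives. There were 94 pairs of neighbouring tested genes that both rose at least 2-fold, against 44.2 ± 6.24 in permutations within abundance deciles (SD over 10000 permutations, permutation p = 0.0001, the smallest they can give). Pairs that both fell numbered 179, against 106 ± 9.43 (permutation p = 0.0001). With overlapping genes left out, the counts were 83 against 41.4 and 168 against 99.0. Runs of at least 4 such genes occurred in 11 places, 5 of them higher and 6 lower, where 1000 permutations gave 0.897 on average and 5 at most. On chromosome 16 from 59666775 to 60018283, 4 genes rose by log2 fold changes from 1.18 to 3.81. On chromosome 2 from 248178389 to 248293784, 4 genes rose by 2.01 to 2.57, and their summed expression went from 30.9 ± 3.17 to 152 ± 39.7 CPM (SD, n = 4 each). On chromosome 15 from 33605654 to 33656089, 4 genes fell by log2 fold changes from -1.56 to -3.32, and their summed expression went from 11458 ± 2107 to 3450 ± 2000 CPM (SD, n = 4 each). In the run on chromosome 15, each gene overlaps another, since 2 of the genes lie within the other 2, so their counts are uncertain. The 2 inner genes were scarce (average log2 CPM -0.016 and -0.955, against 10.9 and 12.4), so the summed expression was almost all that of the outer 2. Overlapping genes were not left out of the runs, and the run on chromosome 5 also held an overlap. Neighbours were set by order among the tested genes, not by distance. The runs spanned from 50.4 kb on chromosome 15 to 1483 kb on chromosome 7. Closely spaced entries on the same strand were not merged, as in the chromosome 7 run (101138549 to 101138860 and 101139376 to 101140308). The number of runs was 17 without ADGRF5 replicate 1, 7 without replicate 3, 6 without replicate 4, and 7 with no filter on low counts. It was 19 without ADGRF5 replicates 1 and 2, and 5 without ADGRF5 replicates 3 and 4; the permutations were not repeated for these fits.

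**Figure D5:**
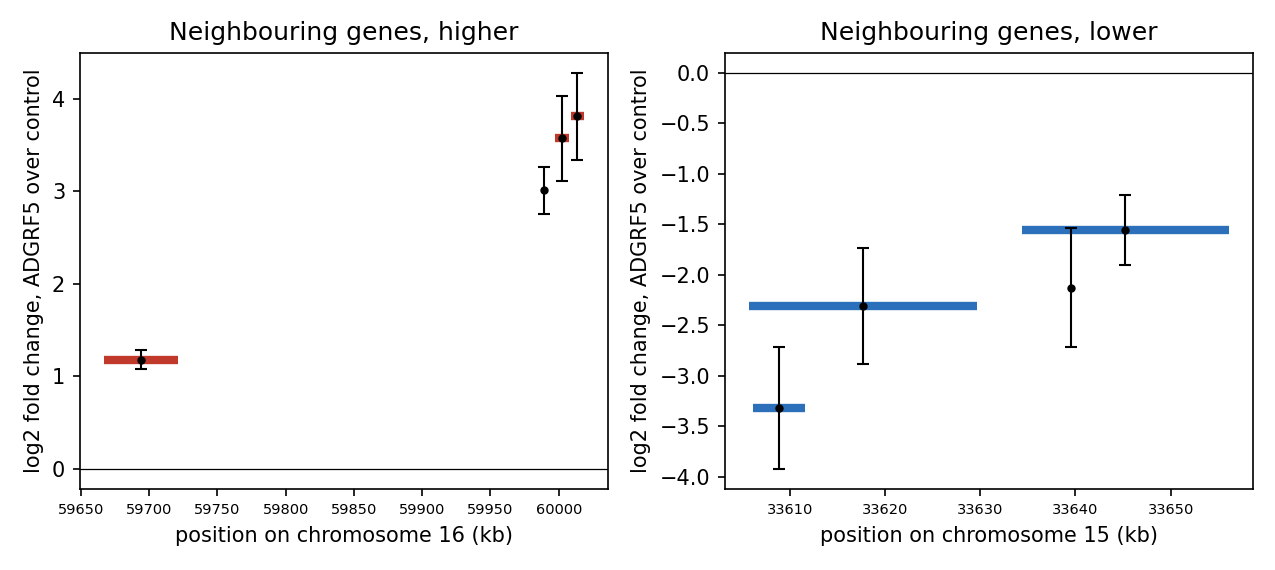
Genes of the runs on chromosomes 16 (higher) and 15 (lower) with the largest median change, as horizontal bars from start to end in kb at their log2 fold change (ADGRF5 over control). Points mark gene centres and error bars are the SE of the fit over 8 libraries; the changes range from 1.18 to 3.81 and from -3.32 to -1.56.

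The authors' deposited table lists 2039 genes, 815 higher and 1224 lower. Its headers do not name the numerator of the fold change, so the overall direction was set here from the sign of the counts. Agreement in overall direction is given by that choice. Both results come from the same 8 libraries, so agreement from gene to gene checks the calculation and gives no independent support. Of the 2039 genes, 1971 were called here by edgeR in the direction that the authors' deposited table gives. In the other direction 0 were called, and 54 did not pass the filter on low counts. Of the 1971 genes called here with at least a 2-fold change, 1953 are in the authors' deposited table. The 3 genes of lowest adjusted p that rose in the authors' deposited table lie on chromosome 3 from 13838304 (log2 fold change 2.76), chromosome 7 from 60719066 (1.37) and chromosome 12 from 48658283 (2.78). The 3 that fell in the authors' deposited table lie on chromosome 1 from 218569510 (-1.87), chromosome 13 from 48607308 (-1.35) and chromosome 7 from 107895045 (-1.40).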

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

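All tests of explanations in this part were chosen after the results they bear on had been seen. Among 42 groups of 4 library values examined, 4 held a library far from the other 3 by Dixon's criterion, which chance meets in about 1 of 20 groups. Control 2 had a total of 35446083 counts, where the other controls had 21410822 to 23061933. Control 1 had the smallest gap between the median log2 CPM of the highest 2 and lowest 2 abundance deciles, 6.48, where the other controls had 6.61 to 6.63. In the run of genes on chromosome 13 that starts at 111926442, control 1 had a summed expression of 219 CPM, where the other controls had 273 to 282 CPM. The remaining one is taken up next.

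Control 4 had 64.0 CPM of the chromosome 9 gene, where the other controls had 15.4 to 20.04 CPM, and it lay nearest to the ADGRF5 libraries on the first principal component. If reads or RNA from ADGRF5 libraries had been carried over, the excess of that gene sets their share at 0.0686% of control 4, which predicts a median shift of 0.000727 (log2) over the 2128 genes changed at least 2-fold between ADGRF5 and the other 3 controls. The shift measured was 0.259, against 0.0537 or less for each other control left out in the same way, which argues against carry-over at that share as the cause of the wider shift. For the chromosome 9 gene alone carry-over stays open: the same share predicts 0.18 counts of the chromosome 12 gene in control 4, too few to test. No biological explanation was tested, since the labels give none for a difference among controls.

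The 4 ADGRF5 libraries differed in their distance from the controls, with first component values from -61.7 to -23.7. A composition effect of the chromosome 9 gene would move risen and fallen genes of a library in the same direction, but in each library their median deviations from the other 3, over genes called without that library, had opposite signs and differed by at least 0.454 (log2). The first component sets the groups apart, so a spread along it largely fixes these opposite signs. They describe that spread and are not a separate test of composition. A different share of cells carrying the chromosome 9 gene's transcript was also examined. With 1 level and 1 response per such cell, it would give each risen gene the ratio between libraries that the chromosome 9 gene has. Over the 6 pairs of libraries the percent of 552 risen genes within 1.5-fold of that ratio was as low as 32.6% and as high as 97.5%, which argues against this form of the explanation; within 1.5-fold of the genes' own median ratio it was at least 67.0%. A dose of virus per cell that differed between cultures was not tested and stays open.

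The mitochondrial share of counts was lower in each ADGRF5 library than in each control. Dilution by the chromosome 9 gene alone would leave no difference once that gene is taken out of the totals, but the log2 ratio of the mean shares was then -0.415, and the nearest libraries were 0.685 percentage points apart, where the controls had an SD of 0.265. Dilution by all risen genes together cannot be told apart from a fall of the mitochondrial transcripts: relative to the median of all tested genes, the mitochondrial genes of at least 200 nt differed by -0.375 (log2), but the nearest libraries of both groups were only 0.0212 apart, within the control SD of 0.0514. An effect of infection or of ADGRF5 on these transcripts stays open, as the design does not part them.

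The number of changed genes was larger for the grouping by treatment than for other groupings of the libraries. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many as 7743 changed genes, which was the split by treatment, and the highest of the others gave 0. The same held for the 1971 genes changed at least 2-fold, again with 1 of 35 splits and 0 for the highest of the others. Each other split mixes ADGRF5 and control libraries within its groups, so the treatment difference adds to the spread there. Their counts of 0 therefore do not show how many genes would be called without a treatment difference. All 35 splits treat the 8 libraries as independent. With the close pairs of libraries taken as 1 replicate each, 2 against 3 replicates are too few to reach a share under 0.05. For the chromosome groups called by camera the treatment split gave 0 and the highest other split 1; with a value of 0, all 35 splits give as many by construction, so the splits say nothing there.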

How the results depend on the processing

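The fits without ADGRF5 libraries 1 and 2 or 3 and 4, without mitochondrial genes, and with close pairs of libraries summed were chosen after the data were examined. With each close pair of libraries (ADGRF5 1 and 2, ADGRF5 3 and 4, controls 2 and 3) summed into 1 replicate, 4819 genes changed instead of 7743, and 2271 fell instead of 3941, with 2 against 3 replicates in the fit; 1631 of the 1971 genes changed at least 2-fold were still called in the same direction. Under all other alternatives run, the number of changed genes stayed within 1.5 times 7743, from 5576 at an adjusted p of 0.01 to 8048 without ADGRF5 libraries 1 and 2. Under all alternatives the number changed at least 2-fold stayed within 1.5 times 1971, from 1438 without ADGRF5 libraries 3 and 4 to 2862 without libraries 1 and 2. Leaving out single libraries gave 6703 to 7710 and 1751 to 2328, and between 1857 and 1946 of the 1971 genes were still called in the same direction. Genes that fell at least 2-fold numbered 1196, 1821 without ADGRF5 libraries 1 and 2, and 837 without libraries 3 and 4; the cause was not tested. The overlap with the authors' deposited table ranged from 1650 to 2006 genes. The 4 genes named by identifier kept their direction and passed the test in each alternative that tested them. The median log2 fold change of the mitochondrial genes was negative in each alternative, from -0.71 to -0.15, and their set passed camera, which it did not with all libraries (median -0.41), with library totals (-0.51), with the replicate block (-0.44) and without ADGRF5 libraries 1 and 2 (-0.71); the cause was not tested. With an estimated correlation these calls did not hold (adjusted p = 0.99, 0.96 and 0.70), and the set passed in no alternative. With single libraries left out, the median lay between -0.51 and -0.32, and it passed without ADGRF5 replicate 1, ADGRF5 replicate 2 or control replicate 1.

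The replicate numbers were not taken to pair the libraries: correlations of deviations between libraries of the same number ranged from -0.174 to 0.322, and 2 of 4 ADGRF5 libraries correlated best with the control of their own number. Libraries of different number also correlated: ADGRF5 1 with controls 2 and 3 (0.239 and 0.224), ADGRF5 2 with control 3 (0.222) and ADGRF5 3 with control 4 (0.260). A batch shared across the groups, which the labels do not give and no fit here models, was not tested. With the replicate block, 7474 genes changed, 1977 of them at least 2-fold, and 4 chromosome groups passed fry instead of 14; with no filter on low counts 8 passed. Alternatives for Adgrf5, the symbol lists and the cell type markers, and the fit without Adgrf5, were not run, since the files do not pair identifiers with symbols. Depth limits calls of scarce genes: 3 counts are 0.0846 to 0.148 CPM.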

Other observations

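The tests in this part were chosen after the data were examined. The 8 most abundant mitochondrial genes among the 50 most abundant genes included 4 that fell and 0 that rose. Of the 42 nuclear genes among these 50, 14 rose and 17 fell, and at least a 2-fold change was reached by 5 in each direction. Single-exon genes numbered 713 among the tested genes, of which 137 rose and 151 fell. Of the genes changed at least 2-fold, 13.2% overlap a gene on the opposite strand, against 14.3% of all tested genes; counts of such pairs are uncertain where strand was not used.

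A candidate source of the chromosome 9 gene's counts is the ADGRF5 transcript that the adenovirus carries. This is a hypothesis, since the files do not pair the identifier with a symbol. It predicts a rise that the neighbouring genes do not share and that no other gene reaches. The 5 tested genes on either side had a median log2 fold change of -0.576, with a range from -2.08 to 0.22, and the next largest rise among all tested genes was 7.81. That gene was already known to have the largest rise, so the last value tests nothing. A rise of the cells' own copy of that gene is not excluded by this test, since it too could leave the neighbours unchanged.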
